A study of Mus musculus with 90 samples.

How the data were processed

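Total RNA of mouse bone marrow-derived macrophages was sequenced, and 90 libraries in 38 groups were used here, 24 groups of 2 and 14 groups of 3. Groups and replicate numbers were taken from the sample titles. Per the file headers, reads were mapped to mm10 with Tophat and gene levels calculated with Partek, and the deposited table of 24543 genes is in RPKM, reads per kilobase of gene and per M alignments. The submitters' processing notes also list CASAVA 1.8.4, bcl2fastq 2.17.1, TopHat2 2.1.0, Partek and deepTools without their roles, and the gene annotation behind the table is not given in the sources used here. The authors' tables of the osteoclast comparisons hold group means as log2 of RPKM + 0.1, ratios of KO over WT or of a construct over hIRF8-WT as linear ratio values, and q-values, deposited in a unit recorded as other. The authors' log2 means equal those of the libraries used here for KO, WT and the day 4 constructs. For the constructs at days 0 and 8 they do not, apart from mock at day 0. Other libraries may have entered those means, which was not tested, and the first header line of the day 0 construct table names day 4. Only the q-values of these tables are printed.

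RPKM divides by the alignments of a library, so a set of transcripts that takes a large share of a library lowers the value of the others. The sum of RPKM ran from 346395 to 592527 per library. The header gives alignments of 0.218 to 122 M per library (second lowest 15.6, median 41.1). As counts per gene were not used here, no count-based interval is given, and the error of a value is the SD between libraries. Gene levels count every read on a gene, so a transcript with a deleted exon is not told from an intact one, and reads of the human constructs that map to mouse Irf8 count as Irf8. Reads of near-identical genes and pseudogenes cannot be placed with certainty.

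In each of the 3 experiments (17, 33 and 40 libraries), genes with at least 1 RPKM in at least 2 libraries were tested: 11530, 11374 and 11237 genes. A linear model with one mean per group was fitted to log2 of RPKM + 1 with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), with 11, 21 and 20 residual degrees of freedom. Tests were two-sided, and Benjamini-Hochberg adjustment was made over the genes of each of 28 contrasts, with a threshold of 0.05. The limma test assumes that groups share a spread, and groups of 2 rest on the spread of the other groups. Contrasts were KO against WT at each day, each later day against day 0 within a genotype, the interaction of genotype and day, each construct against mock or hWT at each day, the altered constructs against each other over days 0 and 4, and in macrophages each construct over the 5 conditions, the mock response to IFNg and to 1, 4 and 8 h of LPS over IFNg, and the interaction of hWT with IFNg and with 4 h of LPS. A fold is 2 to the power of the size of the log2 fold change.

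For lists, 20 sets were written before the data were examined, as were the contrasts, most alternative settings and the rule for named genes: osteoclast effector, osteoclast transcription and RANK signalling, negative regulators of osteoclast formation, type I interferon-stimulated, interferon-gamma-induced GTPases and chemokines, MHC class II presentation, MHC class I presentation, LPS-induced inflammatory, macrophage identity, lysosome and V-ATPase, oxidative phosphorylation, proliferation, neutrophil and granulocyte precursor, dendritic cell, stromal and osteoblast, B cell, T and NK cell, mast cell and basophil, erythroid, and sex-linked genes. Each was compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Lists with a single tested gene are given by that gene. Members passing are counted by the adjustment over all genes. For the lists described in the contrasts written beforehand, the count by adjustment over the list alone is added where it differs. It is not added for alternative settings, for fits without the shallowest library or for contrasts chosen after the data were seen, where it can differ as well. The named genes are Irf8, then the 6 largest rises and 6 largest falls of each KO against WT contrast (4 and 4 elsewhere) past the threshold, with no overlap between the libraries of both groups for contrasts of groups at 1 day or condition, and without predicted or unnamed models, then up to 4 members of each described list with the smallest adjusted p and up to 2 of the highest level that did not pass. A contrast is given with fewer genes than this. Genes named because a count was 5 or fewer, and the genes given for other cell types, were chosen after their values were seen.

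The genes lower in KO at day 0 with a log2 fold change of -1 or below formed a set that was tested by camera in each construct against mock at day 0. The run of each library was inferred from the prefix of its column name in the table. Whether a prefix marks a single sequencing run is not known, so a run here means a shared prefix. Every osteoclast library came from one run except the 3 hWT libraries of day 4. In macrophages, the untreated libraries and the IFNg libraries of mock, hWT and hG388S came from one run. The h379_389 IFNg libraries, all libraries of 1 h LPS and mock at 4 h came from a second, and the rest from another. The comparison of hG388S with hWT in macrophages thus lay within runs in every condition. Where run and group coincide no value within a run can be had.

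The alternative settings written then were a pseudocount of 0.1, no filter, median-of-ratios scaling (each library divided by its median ratio to the geometric mean over genes), replicate number as a block, a fit on the groups of the contrast alone, each library left out in turn, and for the set of genes lower in KO an estimated correlation and a set of all genes past the threshold. After the data were seen, 3 were added: a spline with 4 degrees of freedom of each library's deviation on gene length subtracted before the fit, the endogenous contrasts without the 4 libraries whose deviation correlated with length below -0.3, and the macrophage contrasts over the 4 conditions in which both constructs shared a run. Counts without the shallowest library were among the libraries left out in turn. Gene length was the union of exons, found for 23886 genes (97.3%), and gene positions came from a GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, which may not be the annotation of the authors.

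The fit was tested on data simulated from the fitted group means, with normal noise at each gene's residual SD. That SD was the same in every group, so unequal spread between the real groups was not tested. Changes were planted in genes at or above the median level. At a planted 2-fold change, 49.3% of 67 genes were recovered in a comparison of 3 with 3 libraries of the first experiment, 97% in the second, 88.1% for 2 with 2 macrophage libraries and 98.5% for the average over 5 conditions, with 1.8% to 8.1% false calls. Computation also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.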

Results

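RNA was measured by sequencing in 90 libraries of mouse bone marrow-derived macrophages, cells grown from bone marrow with the growth factor M-CSF, in 3 experiments. In the first, cells with an intact Irf8 gene (WT) and cells without it (KO) were taken with M-CSF alone (day 0) and after M-CSF and RANKL, the cytokine that turns such cells into bone-resorbing osteoclasts, at days 4 and 8. It held 17 libraries, 3 per genotype and day except 2 for WT at day 4. In the second, KO cells carrying human wild-type IRF8 (hWT), human IRF8 with the change G388S (hG388S), a construct named hIRF8379-389 in the labels (h379_389), or a control called mock were followed over the same days in 33 libraries, 3 per group at days 0 and 4. At day 8, h379_389 had 3 libraries and the other constructs 2 each. In the third, the same 4 kinds of cell were sampled as macrophages untreated, with interferon-gamma (IFNg), and with IFNg and bacterial lipopolysaccharide (LPS) for 1, 4 or 8 h, in 40 libraries with 2 per group. Depth ran from 0.218 to 122 M alignments per library, with a median of 41.1 M. The shallowest was the first replicate of untreated hWT macrophages, and the next held 15.6 M.

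Levels are given as mean RPKM ± SD over the libraries of a group, and differences as log2 fold changes of RPKM + 1 with the standard error of the limma fit, which understates the fold of genes near or below 1 RPKM. A gene that changed had a Benjamini-Hochberg adjusted p under 0.05. The p-values measure only the spread between these libraries, and the labels do not say whether replicates of a group are separate animals or portions of one culture. List tests compare a list fixed beforehand with all other genes by camera, adjusted over the lists of a contrast.

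Irf8 encodes a transcription factor of macrophages and dendritic cells and lies on mm10 chromosome 8 at 120736358 to 120756694 on the plus strand (protein coding). Its transcript was still counted in KO cells, at 33.3 ± 0.85 RPKM at day 0 (n = 3) against 72 ± 2.57 in WT (n = 3; log2 -1.09 ± 0.19, adjusted p = 0.000292). At day 4 it stood at 7.11 ± 1.63 RPKM in KO (n = 3) and 22.1 ± 7.07 in WT (n = 2; log2 -1.49 ± 0.22, adjusted p = 0.000177). At day 8 the levels were 6.57 ± 0.454 and 10.1 ± 2.37 RPKM (n = 3 each), a difference that did not pass (log2 -0.52 ± 0.19, adjusted p = 0.0503). These are counts over the whole gene and do not separate intact from disrupted transcripts.

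The comparison of KO with WT at day 0 asks what the absence of Irf8 changes in precursors before RANKL. Genes of cell division stood far higher in KO: all 20 members of the proliferation list were higher, with a mean log2 fold change of 3.94 (camera adjusted p = 2.22e-20, and adjusted p = 0.0228 with an estimated correlation). Ccnd1, the G1 cyclin D1 (chromosome 7, 144929931 to 144939925), reached 242 ± 4.29 RPKM in KO and 2.62 ± 0.429 in WT (log2 6.07 ± 0.26, adjusted p = 6.44e-11, n = 3 each). Top2a, a topoisomerase of dividing cells, stood at 93.4 ± 1.66 and 1.37 ± 0.284 RPKM (log2 5.32 ± 0.23, adjusted p = 9.78e-11). The chemokine Ccl2 was 50.5-fold higher in KO. The complement component C1qb (chromosome 4, 136880129 to 136886187) stood at 8.28 ± 0.925 RPKM in KO and 1690 ± 43.4 in WT (log2 -7.51 ± 0.31, adjusted p = 5.44e-11, n = 3 each), and Ly86, a partner of the receptor RP105, at 0.274 ± 0.076 and 182 ± 5.47 RPKM (log2 -7.17 ± 0.18). Apoe, the carrier of cholesterol, had 569 ± 24.9 RPKM in KO against 8220 ± 422 in WT.

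Both interferon-response lists were lower in KO at day 0. Of 26 type I interferon-stimulated genes, 22 fell (23 adjusted over the list alone; camera adjusted p = 1.5e-15, and adjusted p = 0.0228 with an estimated correlation). Of these, Ifit3 stood at 0.914 ± 0.381 RPKM in KO and 21.9 ± 1.44 in WT (log2 -3.60 ± 0.22, adjusted p = 2.76e-09). Bst2, which tethers virions, was one of those that did not pass, at 81.5 ± 4.55 and 81.6 ± 2.83 RPKM. The interferon-gamma-induced GTPases and chemokines were lower for 12 of 13 (camera adjusted p = 6.07e-11, and adjusted p = 0.0361 with an estimated correlation), with Gbp2 at 2.61 ± 0.357 against 30.5 ± 1.85 RPKM. Of 10 MHC class II presentation genes, 8 were lower (camera adjusted p = 1.3e-07), with H2-Ab1 at 19.3 ± 0.331 against 126 ± 14.2 RPKM, a call not kept with adjusted p = 0.0716 with an estimated correlation. MHC class I genes were lower for 6 of 13 (adjusted p = 0.188 with an estimated correlation). Neutrophil and granulocyte precursor genes were higher for 7 of 10, among them the granule gene Ngp at 24.9 ± 3.27 against 2.95 ± 0.775 RPKM (adjusted p = 0.0638 with an estimated correlation for the list), while the receptor Csf3r of the same list was lower. In all, 4638 of 11530 genes changed, 3058 higher and 1580 lower in KO. Median-of-ratios scaling, which shifts the median log2 fold change by 0.20, put 2274 genes higher and 2333 lower, and a fit on the groups of the contrast alone called 9575.

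The same comparison at day 4 asks how forming osteoclasts differ between the genotypes. Osteoclast effector genes, which serve fusion and bone resorption, were higher in KO for 13 of 20 members (17 adjusted over the list alone), with a mean log2 fold change of 0.94 (camera adjusted p = 1.06e-14, and adjusted p = 0.00666 with an estimated correlation). Dcstamp, needed for cell fusion, stood at 303 ± 19.4 RPKM in KO (n = 3) and 134 ± 4.08 in WT (n = 2; log2 1.17 ± 0.14, adjusted p = 3.52e-05), and the protease Mmp9 at 10400 ± 3650 and 3970 ± 1660 RPKM (log2 1.40 ± 0.27, adjusted p = 0.00234). Mmp14, another protease of the list, had 329 ± 95.5 and 240 ± 47.6 RPKM and did not pass (adjusted p = 0.255). The list's summed RPKM took 11% ± 3.23 of the total in KO at day 4 and 3.96% ± 0.936 in WT. All 26 type I interferon-stimulated genes were lower in KO, by a mean log2 fold change of -2.86 (camera adjusted p = 3.55e-39, and adjusted p = 0.000635 with an estimated correlation). Zbp1, a sensor of nucleic acids, stood at 0.15 RPKM in KO and 16.8 RPKM in WT (log2 -3.95 ± 0.15, adjusted p = 3.2e-10).

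Presentation and macrophage genes were also lower in KO at day 4. The class II list was lower for 9 of 10 genes (adjusted p = 0.0357 with an estimated correlation), the class I list for 11 of 13 (12 adjusted over the list alone; adjusted p = 0.0498 with an estimated correlation) and the interferon-gamma-induced list for 12 of 13 (adjusted p = 0.0136 with an estimated correlation). Ctss, the protease that trims the class II invariant chain, had 179 ± 51.4 RPKM in KO and 2540 ± 741 in WT. Macrophage identity genes were lower for 11 of 20 and higher for 1, the scavenger receptor Marco (camera adjusted p = 2.6e-07, and adjusted p = 0.0136 with an estimated correlation); the high-affinity Fc receptor Fcgr1 had 0.261 RPKM in KO and 15.9 RPKM in WT. Of 12 negative regulators of osteoclast formation, 6 were lower (camera adjusted p = 0.000145, and adjusted p = 0.0549 with an estimated correlation). The osteoclast transcription and RANK signalling list was higher for 4 of 20 and lower for 3 (camera adjusted p = 0.0519). In all, 1545 genes changed, 353 higher and 1192 lower. Scaling, which shifts the median by -0.15, gave 893 higher and 1037 lower. A fit on the groups of the contrast alone called 258 genes, 9 higher and 249 lower. The SD over genes of a library's deviation from its group mean was 0.26 to 0.487 at day 4. At day 0 it was 0.059 to 0.081, so a spread shared over the days is small for day 4. The count was 2954 without the KO library numbered 3. The libraries numbered 3 of both genotypes had a trend of level with gene length (correlations of -0.39 in KO and -0.474 in WT). Leaving out these 2 and the 2 KO libraries of day 8 with a like trend was an alternative chosen after the data were seen. It leaves 1 WT library at day 4, as does leaving out the WT library numbered 1, so no conclusion is drawn from the count of either.

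At day 8 the effector list was higher in KO for 7 of 20 genes (camera adjusted p = 7.15e-05, and adjusted p = 0.127 with an estimated correlation). Acp5, tartrate-resistant acid phosphatase (chromosome 9, 22126727 to 22135711), had 9780 ± 2210 RPKM in KO and 4410 ± 312 in WT (log2 1.12 ± 0.23, adjusted p = 0.00329, n = 3 each). Car2, the carbonic anhydrase that supplies protons for resorption, had 150 ± 19 and 51.9 ± 7.38 RPKM (log2 1.51 ± 0.16, adjusted p = 2.64e-05), while Mmp9 at 3780 ± 280 and 3120 ± 224 did not pass (adjusted p = 0.381). The lysosome and V-ATPase list was higher for 10 of 17 genes, all subunits or partners of the proton pump, and lower for Lamp1, Lamp2 and the pump subunit Atp6v0a1 (camera adjusted p = 0.000285, and adjusted p = 0.0316 with an estimated correlation). Oxidative phosphorylation genes were higher for 12 of 19 (camera adjusted p = 2.92e-08, and adjusted p = 0.0767 with an estimated correlation), against 7 of 19 at day 4 and 9 of 19 at day 0. The KO libraries of day 8 had correlations of level with gene length of -0.409 to -0.105 and those of WT of 0.032 to 0.063. With a gene length trend subtracted, an alternative chosen after the data were seen, 10 of the 17 lysosome and V-ATPase genes were higher and 2 lower, and 11 of the 19 oxidative phosphorylation genes were higher (mean 0.54, where it was 0.70 before). Proliferation genes were lower in KO for 11 of 20, with Top2a at 16.7 ± 2.63 against 44.8 ± 1.41 RPKM (adjusted p = 0.000971; adjusted p = 0.41 with an estimated correlation for the list). The scavenger receptor Marco was 7.29-fold higher in KO and C1qb stood at 5.11 ± 2.55 against 135 ± 19.2 RPKM.

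All 6 stromal and osteoblast genes tested were lower in KO at day 8 (camera adjusted p = 4.14e-05, and adjusted p = 0.127 with an estimated correlation). Col1a1, a chain of type I collagen, had 0.582 ± 0.738 RPKM in KO and 77.1 ± 59.3 in WT (log2 -5.32 ± 0.59, adjusted p = 4.37e-05), and Acta2, smooth muscle actin, 3.03 ± 3.88 and 175 ± 118 RPKM. In WT, Col1a1 was 3.13 ± 2.19 RPKM at day 0, and the interaction of genotype and day was -3.55 ± 0.84 on the log2 scale (adjusted p = 0.00384). Type I interferon-stimulated genes were lower for 11 of 26 (13 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation). In all, 3600 genes changed, 994 higher and 2606 lower in KO. Scaling, which shifts the median by -0.12, gave 1354 higher and 2310 lower. The count fell to 1740 without the first WT library of day 8 and to 2208 without the second. Leaving out the 4 libraries with a length trend leaves 1 KO library at day 8, so no conclusion is drawn from its count.

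**Figure D1:**
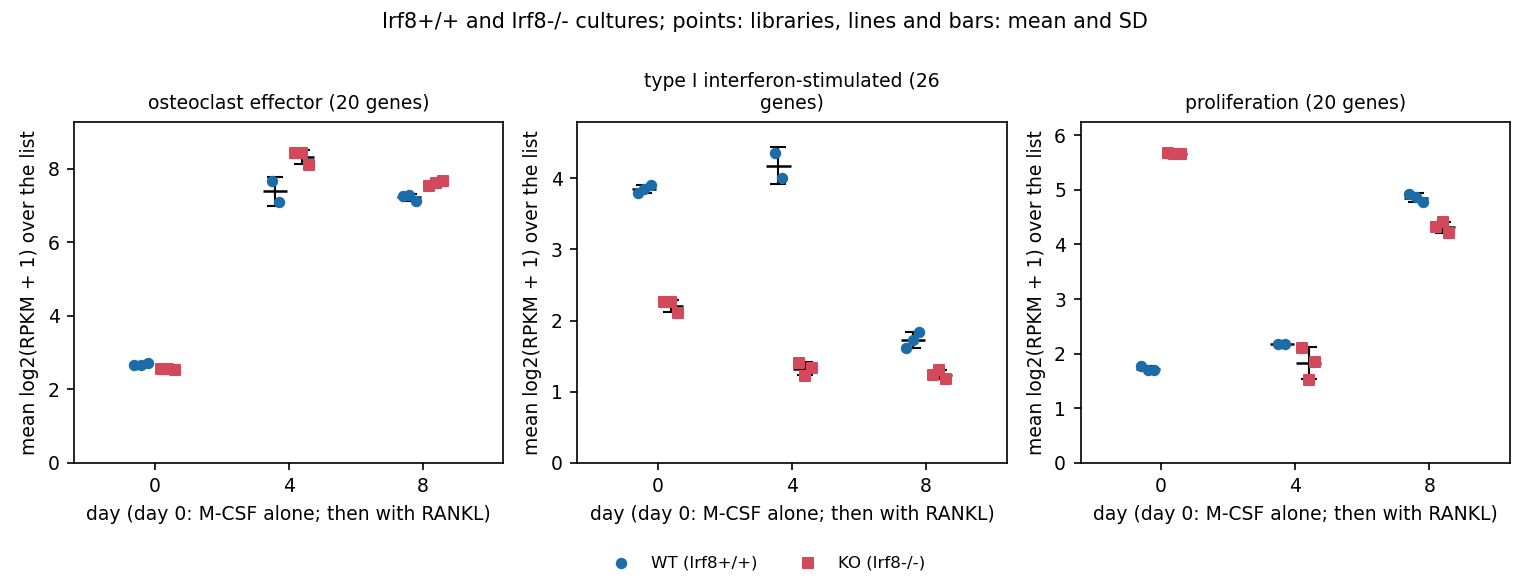
Mean log2(RPKM + 1) over the genes of 3 lists (y axis) by day (x axis; day 0 with M-CSF alone, then with RANKL) in KO and WT cells, where each point is a library and the black line and bar are the mean and SD. At day 4 the effector list lies at 8.1 to 8.44 in KO and 7.11 to 7.67 in WT and the type I interferon-stimulated list at 1.22 to 1.4 and 4.0 to 4.36, while at day 0 the proliferation list lies at 5.65 to 5.68 in KO and 1.7 to 1.78 in WT.

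The change from day 0 to days 4 and 8 within a genotype joins the response to RANKL with the time in culture. No group had M-CSF alone at day 4 or 8, so these cannot be told apart. In WT, 19 of 20 osteoclast effector genes rose by day 4, by a mean log2 fold change of 4.7 (camera adjusted p = 1.15e-23, and adjusted p = 0.00174 with an estimated correlation). Ctsk, the protease cathepsin K that degrades bone collagen (chromosome 3, 95499256 to 95509362), rose from 3.24 ± 1.54 RPKM (n = 3) to 6500 ± 1260 (n = 2; log2 10.62 ± 0.28, adjusted p = 5.31e-13) and stood at 6020 ± 1170 RPKM at day 8. All 19 oxidative phosphorylation genes rose by day 4 (adjusted p = 0.0096 with an estimated correlation), and 12 of 17 lysosome and V-ATPase genes rose while 4 fell (adjusted p = 0.00527 with an estimated correlation). The transglutaminase subunit F13a1 stood at 143 ± 6.7 RPKM at day 0, at 0.589 RPKM at day 4 and is listed at 0 at day 8. By day 8 all 20 proliferation genes had risen (mean 3.13, adjusted p = 0.0255 with an estimated correlation), 24 of 26 type I interferon-stimulated genes had fallen (mean -2.12, adjusted p = 0.016 with an estimated correlation) and 15 of 20 macrophage identity genes had fallen while 3 rose (adjusted p = 0.016 with an estimated correlation). The 6 stromal and osteoblast genes tested also rose in WT by day 8 (adjusted p = 0.231 with an estimated correlation). The proliferation list mean was 4.77 to 4.93 in the 3 WT libraries of day 8, where Col1a1 was 18.5 to 137 RPKM. Irf8 itself fell from day 0 to day 8 (log2 -2.75 ± 0.19).

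In WT, 4978 genes changed by day 4 (2027 higher, 2951 lower) and 6074 by day 8 (3373 higher, 2701 lower). Without the WT day 4 library numbered 3, the day 4 count was 2044. Scaling shifts the median by -0.13 at day 4.

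In KO, 19 of 20 effector genes rose by day 4, by a mean log2 fold change of 5.77 (camera adjusted p = 2.17e-28, and adjusted p = 0.000777 with an estimated correlation), and Ctsk went from 3.79 ± 0.514 to 15500 ± 3860 RPKM (n = 3 each; log2 11.64 ± 0.25, adjusted p = 2.64e-14). All 20 proliferation genes fell in KO by day 4, by a mean of -3.84 (camera adjusted p = 1.37e-13, and adjusted p = 0.034 with an estimated correlation). The replication helicase subunit Mcm5 went from 57.7 RPKM to 2.18 RPKM, and Ccnd1 was 61.9-fold lower at day 4 than at day 0. Neutrophil and granulocyte precursor genes fell for 9 of 10 (adjusted p = 0.0237 with an estimated correlation). Mrc1, the mannose receptor, stood at 180 ± 2.9 RPKM at day 0 and 5.39 ± 2.01 at day 8. The day 4 change covered 6672 genes (1573 higher, 5099 lower; with scaling 2726 higher and 2920 lower, a shift of the median of -0.47) and the day 8 change 6831 genes (2109 higher, 4722 lower; with scaling 2929 higher and 3655 lower, a shift of -0.27).

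Whether the change from day 0, with RANKL and time in culture together, differed between the genotypes was tested by the interaction of genotype and day. By day 4 the effector list rose more in KO for 10 of 20 genes (11 adjusted over the list alone; camera adjusted p = 9.35e-09, and adjusted p = 0.0423 with an estimated correlation), led by Mmp14 (difference of log2 changes 3.82 ± 0.30, adjusted p = 1.91e-07) and Atp6v0d2, a pump subunit used in fusion (2.85 ± 0.32, adjusted p = 8.59e-06). Both started lower in KO, with Mmp14 at 0.321 ± 0.0508 against 12.8 ± 0.742 RPKM and Atp6v0d2 at 2.37 ± 0.202 against 12.4 ± 0.538 RPKM at day 0. For Ctsk the difference was 1.01 ± 0.37 and did not pass (adjusted p = 0.057). All 20 proliferation genes had a lower change in KO, by a mean of -4.30 by day 4 (adjusted p = 0.025 with an estimated correlation) and -4.48 by day 8 (adjusted p = 0.0461 with an estimated correlation). Most of this is the gap at day 0, as KO over WT had a mean of 3.94 at day 0, -0.36 at day 4 and -0.54 at day 8. Id1 and Id3, inhibitors of helix-loop-helix transcription factors, had interactions of -6.34 and -6.36 at day 4. By day 8 the type I interferon-stimulated list fell less in KO for 16 of 26 genes and more for 1 (camera adjusted p = 7.57e-11, and adjusted p = 0.05 with an estimated correlation), starting from lower levels. The interactions covered 3182 genes by day 4 (675 higher, 2507 lower in KO; with scaling 1477 and 1576, a shift of -0.35) and 4356 by day 8 (1162 higher, 3194 lower; with scaling 1821 and 2275, a shift of -0.32). Leaving out the 4 libraries with a length trend leaves 1 WT library at day 4 and 1 KO library at day 8. No conclusion is drawn from its interaction counts.

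Adding human IRF8 back to KO cells asks which of these genes respond to the construct. Irf8 as counted was higher in hWT than in mock by a log2 difference of 1.314 at day 0, 1.74 at day 4 and 0.974 at day 8 (adjusted p = 6.53e-09, 2.15e-10 and 8.68e-05). At day 0, C1qb stood at 172 ± 53.6 RPKM in hWT and 5.3 ± 0.565 in mock (log2 4.73 ± 0.19, adjusted p = 7.14e-17, n = 3 each), and Ocstamp, a fusion protein of osteoclasts, at 25.5 ± 9.25 and 0.35 ± 0.225 RPKM. Cd5l, a protein secreted by macrophages, stood at 147 ± 15.8 RPKM in mock and 10.5 ± 1.51 in hWT. All 15 neutrophil and granulocyte precursor genes were lower in hWT (camera adjusted p = 4.12e-05, and adjusted p = 0.26 with an estimated correlation), with the calgranulin S100a9 at 221 ± 43.8 against 572 ± 48.2 RPKM. Proliferation genes were higher for 18 of 20 and lower for 1 (camera adjusted p = 0.00413, and adjusted p = 0.357 with an estimated correlation), with Top2a at 65.9 ± 17.8 against 14.8 ± 2.65 RPKM. In all, 8498 of 11374 genes changed, 5476 higher and 3022 lower. Scaling, which shifts the median by 0.28, gave 4226 higher and 4125 lower, and a fit on the groups of the contrast alone called 5649. The 3 mock libraries had correlations of level with gene length of -0.422 to -0.304 and the 3 hWT libraries of 0.143 to 0.249.

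At day 4 the same comparison asks whether IRF8 holds back the osteoclast program. The effector list was lower in hWT than in mock for 19 of 20 genes, by a mean of -0.53 (camera adjusted p = 5.82e-06, and adjusted p = 0.0139 with an estimated correlation). At day 0 the list's share of summed RPKM ran the other way, at 0.116% ± 0.0115 in hWT and 0.0636% ± 0.00247 in mock. Acp5 stood at 985 ± 74.1 RPKM in hWT and 2060 ± 31 in mock (log2 -1.06 ± 0.14, adjusted p = 1.09e-06, n = 3 each), and Dcstamp at 71.7 ± 5.85 and 123 ± 3.17 RPKM. The lysosome and V-ATPase list was lower for 14 of 17 genes, with the protease Ctsd at 1410 ± 90.4 against 3710 ± 224 RPKM (adjusted p = 0.00744 with an estimated correlation for the list). All 10 class II presentation genes were higher, by a mean of 2.5 (camera adjusted p = 8.2e-12, and adjusted p = 0.00744 with an estimated correlation), with H2-Ab1 (chromosome 17, 34257689 to 34269419) at 231 ± 6.11 against 12.9 ± 1.78 RPKM (log2 4.07 ± 0.14, adjusted p = 6.4e-18). Dendritic cell genes were higher for 6 of 7 (adjusted p = 0.00744 with an estimated correlation), among them the receptor Clec9a at 7.76 ± 0.405 against 0.0593 ± 0.0211 RPKM. Plbd1, a phospholipase-like lysosomal protein, showed the largest rise, at 181 ± 10.5 against 1.67 ± 0.205 RPKM (log2 6.09 ± 0.11).

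Of 12 negative regulators of osteoclast formation, 8 were higher in hWT at day 4, including the Notch effector Rbpj and Id3 (camera adjusted p = 0.00312, and adjusted p = 0.0516 with an estimated correlation). Proliferation genes were higher for 15 of 20 (adjusted p = 0.0517 with an estimated correlation), and the osteoclast transcription and RANK signalling list was lower for 10 of 20 and higher for 1 (adjusted p = 0.205 with an estimated correlation). In all, 5408 genes changed, 2708 higher and 2700 lower. By the column names, the 3 hWT libraries of day 4 came from a run apart from every other osteoclast library. Run and construct thus cannot be told apart there. These libraries had correlations of level with gene length of 0.32 to 0.357 and the mock libraries of -0.045 to 0.168. With a gene length trend subtracted, an alternative chosen after the data were seen, 5254 genes changed. At day 8, within one run, the effector list was lower in hWT for 17 of 20 genes (19 adjusted over the list alone; mean -0.84, camera adjusted p = 2.08e-10, and adjusted p = 0.00142 with an estimated correlation), the lysosome list for 12 of 17 (adjusted p = 0.00142 with an estimated correlation), and class II genes were higher for 9 of 10 (mean 2.13, adjusted p = 0.00223 with an estimated correlation). Mmp14 had 32.2 ± 0.164 RPKM in hWT and 167 ± 8.41 in mock (log2 -2.34 ± 0.14, adjusted p = 8.78e-13, n = 2 each), and the receptor kinase Axl 83.3 ± 0.167 and 0.55 ± 0.259 RPKM. The day 8 count was 3480 (1657 higher, 1823 lower), with 2132 without the first mock library and 2264 without the first hWT library.

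**Figure D2:**
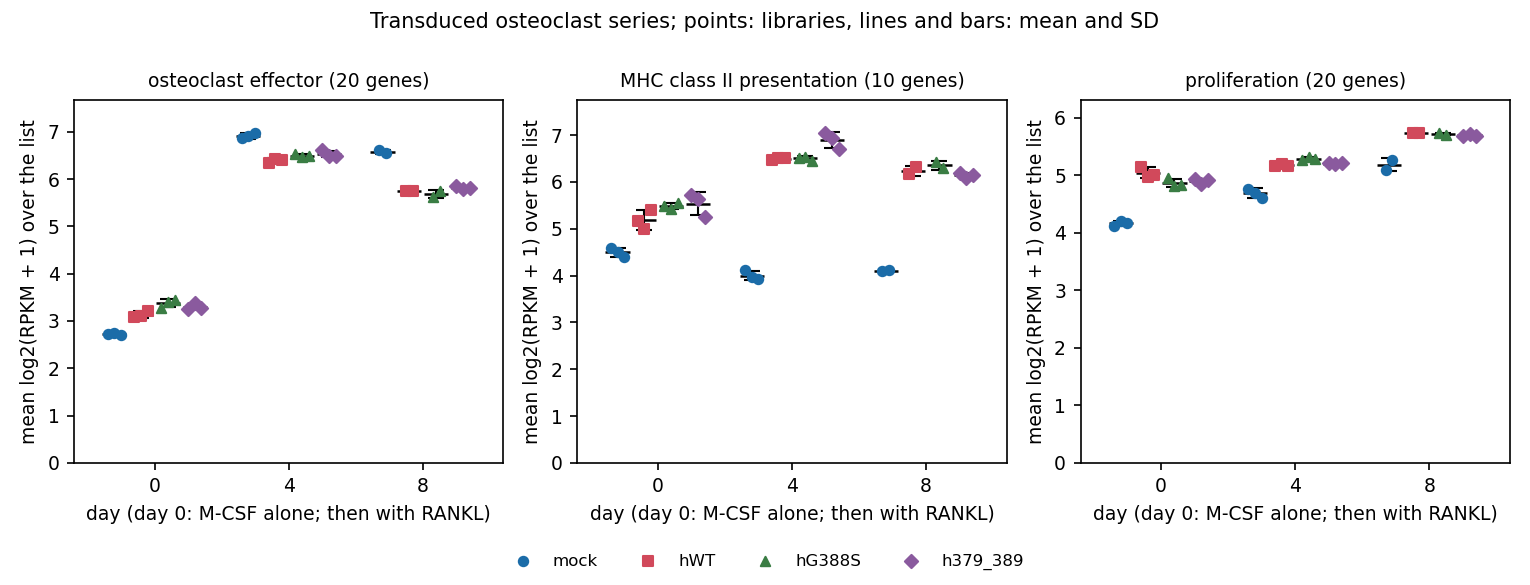
Mean log2(RPKM + 1) over the genes of 3 lists (y axis) by day (x axis) in KO cells with mock, hWT, hG388S or h379_389, where each point is a library and the black line and bar are the mean and SD. At day 8 the effector list lies at 6.55 to 6.61 in mock and 5.62 to 5.85 in the 3 IRF8 constructs, and the class II list at 4.09 to 4.12 in mock and 6.09 to 6.42 in the constructs.

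The genes lower in KO than in WT and the genes changed by hWT were compared as sets, since the series asks what IRF8 controls. Of 10998 genes tested in both experiments, 851 were lower in KO and higher in hWT at day 8 where 343 would be shared if the calls were independent, and 449 were higher in KO and lower in hWT against 158. At day 4 these counts were 441 against 274 and 184 against 79. At day 0 they were 652 against 709 and 697 against 798. In the same direction, 12 were higher and 143 lower in both at day 8, against 139 and 390. These counts were 30 against 77 and 314 against 282 at day 4, and 1576 against 1476 and 403 against 383 at day 0. Genes are not independent replicates, so no p is given for these counts. At day 8, correlations of level with gene length were lower in KO than in WT (-0.409 to -0.105 against 0.032 to 0.063). They were also lower in mock than in hWT (-0.302 and -0.213 against -0.125 and -0.163). A shared length trend may thus add to the overlap at day 8, which was not tested. At day 4, run and construct cannot be told apart for hWT. The 750 genes lower in KO at day 0 by a log2 fold change of -1 or beyond, of which 694 were tested here, had a mean log2 fold change of 0.25 in hWT over mock at day 0, against 0.22 for other genes, while camera, which ranks by the test statistic, placed them below other genes (adjusted p = 0.863 over the 3 constructs). Their mean was 0.39 in hG388S and 0.35 in h379_389, against 0.25 for other genes in both (adjusted p = 0.863 in each).

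Each altered construct was compared with hWT to ask whether the change in IRF8 alters its effect. In hG388S at day 0, Acod1, the enzyme that makes itaconate, stood at 37.2 ± 7.28 RPKM against 11.8 ± 2.97 in hWT (log2 1.58 ± 0.16, adjusted p = 3.56e-06, n = 3 each), and the chemokine Ccl5 at 71.5 ± 7.28 against 29.9 ± 10.8 RPKM (adjusted p = 0.017). Mrc1 was lower, at 3.96 ± 0.681 against 9.22 ± 1.33 RPKM (log2 -1.04 ± 0.16, adjusted p = 0.00107). Of 20 effector genes 5 were higher (8 adjusted over the list alone; camera adjusted p = 0.00124, and adjusted p = 0.117 with an estimated correlation), among them Acp5 and Mmp14. Irf8 as counted did not pass, at 57.2 ± 8.31 and 56.6 ± 14.7 RPKM (adjusted p = 0.903). In all, 87 genes changed, 71 higher and 16 lower, with 2093 at an unadjusted p under 0.05 by limma. A fit on the groups of the contrast alone called 0. Leaving out the third hWT library gave 2508, and leaving out the other two hWT libraries or the second or the third hG388S library gave 44, 29, 28 and 17.

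At day 4, Ccl5 stood at 17.6 ± 1.24 RPKM in hG388S and 3.64 ± 0.284 in hWT (4.01-fold, adjusted p = 2.92e-05, n = 3 each), the transcription factor Myc at 49 ± 2.29 and 30 ± 1.15 RPKM and the protease Ctsb at 1090 ± 41.6 and 754 ± 45.5 RPKM. Fn1, fibronectin, had 0.115 ± 0.0419 RPKM against 6.28 ± 2.78 in hWT (log2 -2.64 ± 0.34, adjusted p = 1.48e-05). The largest rises were of the ribosomal pseudogenes Rplp2-ps1 and Rpl34-ps1, near-copies whose reads cannot be placed with certainty. Lysosome genes were higher for 6 of 17 and RANK signalling genes for 6 of 20 (adjusted p = 0.268 with an estimated correlation in both). Class II genes were lower for 1 of 10 (camera adjusted p = 0.873). The count was 3150 (1560 higher, 1590 lower), with 6210 in a fit on the groups of the contrast alone and 1748 to 2072 when the second or the third hG388S library or the first or the third hWT library was left out. The 3 hG388S libraries of day 4 came from a run other than that of the 3 hWT libraries, so run and construct cannot be told apart. Correlations of level with gene length were -0.02 to 0.15 in these hG388S libraries and 0.32 to 0.357 in the hWT libraries. With a gene length trend subtracted, an alternative chosen after the data were seen, the day 4 count was 2737. At day 8, within one run, 197 genes changed (171 higher, 26 lower), among them the adaptor Cbl at 16.2 ± 1.22 against 6.12 ± 0.465 RPKM (adjusted p = 0.0492, n = 2 each) and the lectin receptor Clec4d at 95 ± 6.47 against 153 ± 7.78 (adjusted p = 0.0157). By limma 2109 genes had an unadjusted p under 0.05. A fit on the groups of the contrast alone called 1974, no filter 116 and a pseudocount of 0.1 called 1. Median-of-ratios scaling left 6 genes, subtracting a gene length trend (an alternative chosen after the data were seen) left 0, and leaving out any of the 4 libraries left 0 to 5 (0 without either hWT library or the second hG388S library, 5 without the first).

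In h379_389 at day 0, limma called 2 genes against hWT, where 789 had an unadjusted p under 0.05. They were Dcstamp, at 24.2 ± 3.47 against 15.2 ± 1.05 RPKM (log2 0.63 ± 0.10, adjusted p = 0.0101, n = 3 each), and the protease inhibitor Serpina3g, a member of a family of near-copies. A fit on the groups of the contrast alone called 0, no filter 4, and a pseudocount of 0.1 or a subtracted length trend 1. The count was 415 without the third hWT library, 15 without the third h379_389 library, 1 without the second h379_389 or the second hWT library and 0 without the first hWT library. At day 4, class II genes were higher for 6 of 10 (camera adjusted p = 0.00891, and adjusted p = 0.379 with an estimated correlation), with the invariant chain Cd74 at 1280 ± 178 against 642 ± 37.6 RPKM (log2 0.98 ± 0.20, adjusted p = 0.000603, n = 3 each). Effector genes were higher for 6 of 20 and lower for 2 (adjusted p = 0.379 with an estimated correlation), with the receptor Oscar at 60.3 ± 6.78 against 34 ± 1.37 RPKM and the integrin Itgb3 at 26.9 ± 1.86 against 41.4 ± 1.16 RPKM. Irf8 stood at 16.2 ± 1.82 against 24.6 ± 1.81 RPKM (adjusted p = 0.00318). Correlations of level with gene length were -0.134 to -0.076 in the h379_389 libraries of day 4 and 0.32 to 0.357 in those of hWT. With a gene length trend subtracted, an alternative chosen after the data were seen, 2747 genes changed. With scaling, 1890 were higher and 1711 lower. The main count was 3665 (1458 higher, 2207 lower), again across runs, and a fit on the groups of the contrast alone called 6173. At day 8 it was 430 (384 higher, 46 lower; 2291 with an unadjusted p under 0.05 by limma), with 5218 in a fit on the groups of the contrast alone, 269 with a pseudocount of 0.1, 0 once a gene length trend was subtracted, an alternative chosen after the data were seen, 117 without the third h379_389 library and 0 without any one of the other 4.

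The altered constructs shared their runs at days 0 and 4, so they were compared with each other over both days. In hG388S, Ccl5 was higher by a log2 fold change of 0.91 ± 0.19 (adjusted p = 0.0244, n = 6 each) and Angptl2, a secreted glycoprotein, by 0.72 ± 0.10 (adjusted p = 0.000395). The prostaglandin-degrading enzyme Hpgd was lower by -0.67 ± 0.10 (adjusted p = 0.00105) and Mrc1 by -0.60 ± 0.11 (adjusted p = 0.0112). Class II genes were lower in hG388S for 2 of 10, H2-Ab1 and H2-Eb1 (6 adjusted over the list alone; camera adjusted p = 8.52e-06, and adjusted p = 0.194 with an estimated correlation). In all, 96 genes changed, 58 higher and 38 lower, and 15 to 51 when any 1 of the 12 libraries but the first hG388S library of day 0 was left out (119 without that one). With a pseudocount of 0.1 it was 54.

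In macrophages, hWT was compared with mock over the 5 conditions to ask what IRF8 adds outside osteoclast culture. Plbd1 was higher by a log2 fold change of 3.79 ± 0.08 (adjusted p = 3.8e-21, n = 10 each), the chemokine Ccl8 by 4.61 ± 0.18 (adjusted p = 1.27e-15) and C1qa by 3.63 ± 0.08 (adjusted p = 1.73e-20). Id3 was lower by -1.78 ± 0.09 and the neutrophil chemokine Cxcl1 by -1.48 ± 0.08. Class II genes were higher for 10 of 11, by a mean of 1.14 (camera adjusted p = 7.46e-11, and adjusted p = 0.00608 with an estimated correlation), and dendritic cell genes for 5 of 6 (adjusted p = 0.00608 with an estimated correlation), among them Clec9a by 2.22 ± 0.07. Of 22 LPS-induced inflammatory genes, 10 were lower, including Il12a (log2 -0.82 ± 0.04) and Il23a (-1.34 ± 0.09), subunits of interleukin-12 and interleukin-23, and Ccl4 and the anti-inflammatory cytokine Il10 (1.48 ± 0.12) were higher (camera adjusted p = 0.00429, and adjusted p = 0.28 with an estimated correlation). Without the shallowest library, class II genes were higher for 9 of 11 and lower for 1 (adjusted p = 0.0349 with an estimated correlation), dendritic cell genes higher for 5 of 6 (adjusted p = 0.00569 with an estimated correlation), and LPS-induced genes lower for 12 of 22 and higher for 3 (adjusted p = 0.247 with an estimated correlation). Irf8 as counted was higher in hWT by 0.32 ± 0.09 (adjusted p = 0.00465), and by 0.20 ± 0.04 (adjusted p = 6.94e-05) without the shallowest library. Untreated, it stood at 73 ± 6.35 RPKM in mock (n = 2), at 64.1 in the deep hWT library and at 146 in the shallowest. The 4006 genes changed were split 1997 higher and 2009 lower. Without the shallowest library, 5147 changed (2716 higher, 2431 lower; 3796 in both). Without the second untreated hWT library, which leaves the shallowest alone in its group, 6906 changed. In the 4 conditions sequenced in one run for both constructs, the count was 3538.

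Against hWT over the 5 conditions, hG388S changed 5 genes with all 20 libraries, where 1613 had an unadjusted p under 0.05 by limma. The adhesion receptor Itga1, Cd93 and the oxidase Ero1lb were higher, and the chemokine Cxcl14 and the histone gene Hist1h2bc, which has near-copies, were lower, all by log2 fold changes of 0.19 to 0.35 in size. No member of any list passed. Without the shallowest library, 27 genes changed (10 higher, 17 lower; 5 in both), and 4 of 15 neutrophil and granulocyte precursor genes were lower (camera adjusted p = 7.95e-09, and adjusted p = 0.0338 with an estimated correlation), among them S100a9 (log2 -0.43 ± 0.08, adjusted p = 0.0183) and Ngp (-0.43 ± 0.08, adjusted p = 0.0145). The count was 5374 without the second untreated hWT library, 21 without the first hWT library of 1 h LPS, 4 without the first untreated hG388S library and 0 to 3 without any 1 of the other 16 deep libraries. It was 20 with no filter and 8 with a pseudocount of 0.1 or with replicate number as a block. In h379_389, 48 genes changed against hWT (34 higher, 14 lower), with Clec9a higher by 0.49 ± 0.07 (adjusted p = 0.000322) and the peptidase Dpp4 by 0.50 ± 0.08 (adjusted p = 0.00303). Dendritic cell genes were higher for 1 of 6 (3 adjusted over the list alone; adjusted p = 0.122 with an estimated correlation). The count was 144 without the shallowest library (48 in both) and also 144 in the 4 conditions sequenced in one run for both constructs. It was 30 with a pseudocount of 0.1. It was 4904 without the second untreated hWT library, and 25 to 31 without the first library of IFNg, 4 h LPS or 8 h LPS of either construct or without either h379_389 library of 1 h LPS.

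The response of mock macrophages to IFNg gives the background for the IRF8 comparisons. Cxcl9, a chemokine for T cells (chromosome 5, 92321347 to 92328079), stood at 1790 ± 169 RPKM with IFNg and 3.06 ± 1.23 untreated (log2 8.82 ± 1.19, adjusted p = 9.46e-07, n = 2 each), and H2-Aa at 634 ± 32 and 40.7 ± 5.56 RPKM (log2 3.93 ± 0.17). All 19 interferon-gamma-induced GTPases and chemokines rose (mean 6.01; camera adjusted p = 1.07e-13, and adjusted p = 0.199 with an estimated correlation), as did all 26 type I interferon-stimulated genes (mean 4.35, adjusted p = 0.199 with an estimated correlation) and 12 of 13 class I genes (adjusted p = 0.199 with an estimated correlation). Class II genes rose for 10 of 11 and fell for the reductase Ifi30 (mean 2.72, adjusted p = 0.0198 with an estimated correlation). Igfbp4, a binder of insulin-like growth factors, fell from 280 ± 13.9 to 3.11 ± 0.357 RPKM. Irf8 rose from 73 ± 6.35 to 163 ± 3.57 RPKM (adjusted p = 1.58e-05). In all, 7098 genes changed (2126 higher, 4972 lower; with scaling 3101 and 3333, a shift of -0.26). The standard errors and estimated correlations of this contrast come from all macrophage groups, the shallowest library included. There Cxcl9 stood at 817 RPKM against 2.34 in its replicate, which widens the spread of such genes. No fit of this contrast without that library is given.

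LPS was added to IFNg to follow the inflammatory response over time. After 1 h, 16 of 22 LPS-induced inflammatory genes had risen (mean 3.74; camera adjusted p = 5.27e-36, and adjusted p = 1.28e-05 with an estimated correlation), with the neutrophil chemokine Cxcl2 at 1970 ± 186 RPKM against 2.03 ± 0.199 with IFNg alone (log2 9.34 ± 0.24, n = 2 each). After 4 h, 20 had risen (mean 6.09, adjusted p = 2.22e-05 with an estimated correlation), with the cytokine Il6 (chromosome 5, 30013114 to 30019981) at 729 ± 125 against 0.0803 ± 0.0652 RPKM, and after 8 h 21 (22 adjusted over the list alone; mean 5.62, adjusted p = 8.04e-05 with an estimated correlation). The list's share of summed RPKM was 0.95% with IFNg and 4.49%, 12.8% and 11.6% after 1, 4 and 8 h. Irf8 had 103 ± 1.21 RPKM at 4 h against 163 ± 3.57 with IFNg (log2 -0.66 ± 0.19, adjusted p = 0.00357), a direction that turned with scaling (0.41, adjusted p = 0.0923). Of 19 oxidative phosphorylation genes, 18 fell and 1 rose at 4 h, and with scaling 5 fell and 6 rose. The counts were 2963 at 1 h (857 higher, 2106 lower; with scaling 1385 and 1088, a shift of -0.15), 8571 at 4 h (1380 higher, 7191 lower; with scaling 3946 and 3542, a shift of -0.87, with 1047 genes called in opposite directions) and 7403 at 8 h (1699 higher, 5704 lower; with scaling 3522 and 3327, a shift of -0.50). At 1 h the count was 1882 without the second IFNg library and 1974 without the first LPS library. The mock IFNg libraries and all 3 mock LPS groups came from different runs, so run and treatment cannot be told apart for mock. In h379_389, whose IFNg and 1 h LPS libraries shared a run, 17 of 22 LPS-induced genes rose after 1 h (mean 3.75, adjusted p = 1.39e-05 with an estimated correlation), a comparison chosen after the data were seen.

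**Figure D3:**
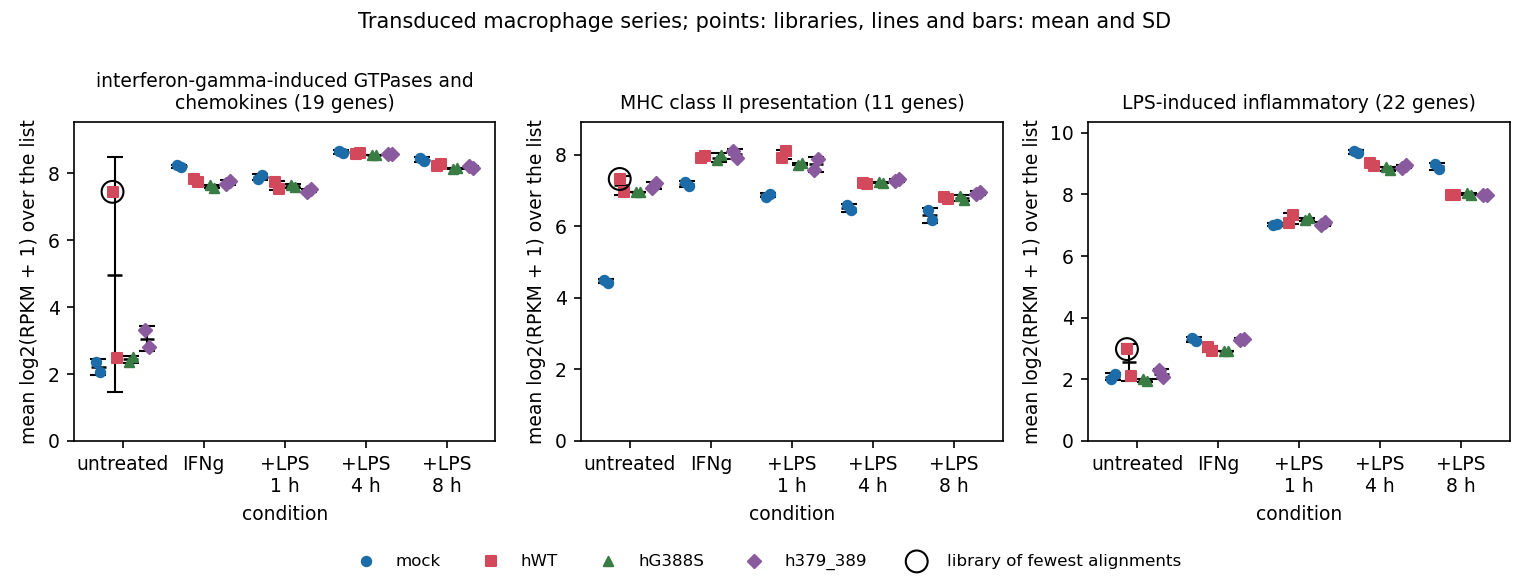
Mean log2(RPKM + 1) over the genes of 3 lists (y axis) by condition (x axis) in macrophages with mock, hWT, hG388S or h379_389, where each point is a library, the black line and bar are the mean and SD, and the open circle is the library of fewest alignments. On the interferon-gamma list the 2 untreated hWT libraries lie at 7.45 (open circle) and 2.49, while untreated mock lies at 2.05 to 2.37, and the LPS-induced list of mock goes from 3.24 to 3.34 with IFNg to 9.34 to 9.42 after 4 h of LPS.

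Whether IRF8 alters the response to IFNg was tested by the interaction of hWT or mock with treatment. Class II genes rose less in hWT for 8 of 11 (9 adjusted over the list alone; mean -1.93, camera adjusted p = 1.71e-13, and adjusted p = 0.0046 with an estimated correlation), with H2-Aa at -3.30 ± 0.25 (adjusted p = 1.25e-08). Without the shallowest library this held for 7 of 11 (mean -1.75, adjusted p = 0.00502 with an estimated correlation), from an untreated list mean of 6.96 in the remaining hWT library and 4.42 to 4.5 in mock. Type I interferon-stimulated genes rose less for 23 of 26 (26 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation) and interferon-gamma-induced genes for 14 of 19 (adjusted p = 0.259 with an estimated correlation), and without the shallowest library for 16 of 26 and 8 of 19 (adjusted p = 0.133 with an estimated correlation in both). In the shallowest library, untreated hWT, Cxcl9 was at 817 RPKM against 2.34 in its replicate. The interaction covered 2870 genes (1910 higher, 960 lower; with scaling 1213 and 1150, a shift of 0.14), 2 in a fit on the groups of the contrast alone (both lower), 1491 without the shallowest library (1158 in both), 7178 without its replicate, and 1528, 1360, 1529 and 1578 without each of the hWT and mock IFNg libraries in turn.

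The interaction at 4 h of LPS over IFNg covered 2741 genes (1059 higher, 1682 lower). Dusp1, a phosphatase of stress kinases, rose more in hWT (3.38 ± 0.24, adjusted p = 6.48e-10), as did the acute-phase protein Saa3 (2.98 ± 0.67, adjusted p = 0.0022). Il23a (-3.62 ± 0.29, adjusted p = 4.59e-09), Il12a (-2.15 ± 0.13, adjusted p = 1.49e-10) and Cxcl1 (-2.55 ± 0.27, adjusted p = 3.04e-07) rose less. Of 22 LPS-induced genes, 6 had a higher and 5 a lower response (camera adjusted p = 0.806). The mock and hWT libraries of 4 h came from different runs. The count was 5815 in a fit on the groups of the contrast alone, 1786 without the first hWT library of 4 h and 1660 without the first mock IFNg library.

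Lists of other cell types had few members past the filter. No erythroid gene was tested in any experiment. The B cell list was represented by Cd79b, which was lower in hWT than in mock at day 0 (log2 -1.72) and in macrophages (-0.50), and changed in no comparison of KO with WT. The T and NK cell list had no gene in the first experiment, Cd3d in the second, which was higher in hWT than in mock at day 4 (0.57), and Lck in macrophages, which rose with IFNg (0.75). The mast cell and basophil list was represented by Gata2 in the first experiment, lower in KO at day 8 (-1.06), and by Hdc in macrophages, which rose with IFNg (2.22) and further with 4 h of LPS (3.83). Of the sex-linked list, Xist alone was tested, lower in KO at day 8 (-1.43) and higher in hWT than in mock at day 0 (2.46). Its transcript is long, and in both cases the libraries with less of it were those of lower correlation of level with gene length (-0.409 to -0.105 in KO against 0.032 to 0.063 in WT, and -0.422 to -0.304 in mock against 0.143 to 0.249 in hWT).

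The deposited tables of the authors hold q-values for the osteoclast comparisons. Under 0.05 they hold 12829 genes for KO against WT at day 0, 1 at day 4 and 4880 at day 8, where limma called 4638, 1545 and 3600. For hG388S against hWT they hold 329, 1422 and 3 genes, for the other altered construct 3, 1272 and 0, and for mock against hWT 10784, 4106 and 4655. The construct means of days 0 and 8, apart from mock at day 0, did not equal those of the libraries used here, so other libraries may have entered them. The authors' genes were not filtered in the same way.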

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

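The tests of 3 patterns were chosen only after the result was seen, apart from the prediction for gene length in the third. The gene length setting behind that prediction was itself added after the data were seen. The other splits of the libraries were planned.

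The change from day 0, with RANKL and time in culture together, differed between genotypes for 3182 genes by day 4 and 4356 by day 8. This was the test of the difference itself. Both counts rest on the day 0 libraries, where the genotypes already differed for 4638 genes, so a gap at day 0 enters them as well as a different rise or fall. The response of hWT macrophages differed from that of mock for 2870 genes with IFNg (2 in a fit on the groups of the contrast alone, 1491 without the shallowest library and 1360 to 7178 when any 1 library was left out) and for 2741 genes with 4 h of LPS over IFNg (5815 in the fit on its groups alone, and 1660 to 2487 when any 1 library was left out).

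The first untreated hWT macrophage library, with 0.218 M alignments, held transcripts that IFNg raises in the other libraries, such as Cxcl9 at 817 RPKM against 2.34 in its replicate. A mislabelled hWT library with IFNg is argued against: over 97 genes raised by IFNg in hWT, the median share of the rise was 0.7 (interquartile range 0.62 to 0.8). A partial response of untreated hWT cells as the whole source is argued against too, since 22 genes that are higher in hWT than in mock lay at a median of -0.56 (log2; -0.82 to -0.39) from the best mixture of untreated and IFNg hWT libraries, 21 of them below it. Reads of the other libraries of its run may account for part of the pattern and cannot be told apart from other sources: against the depth-weighted mean of the run's 13 other libraries the 97 genes stood at a median share of 1.15 (1.0 to 1.26), where 1 is that mean, and the SD of the log2 difference was 0.602 over 4799 genes, above the 0.384 of simulated sampling and close to the 0.613 from the best hWT mixture. The same 22 genes lay below that mean too, at a median of -0.16 (-0.39 to -0.01; 17 below), so reads in proportion to depth do not account for them in full, and other proportions were not tested.

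At day 4, 3150 genes were called between hG388S and hWT and 3665 between h379_389 and hWT. Variation between libraries of one group is a candidate source: the first component of such variation in the 24 transduced libraries outside this contrast, which held 50.8% of it, correlated across genes with the mean difference of the mutants from hWT at 0.62, and at 0.1 with the difference between the mutants. That component was carried by libraries of day 0 (scores of -33.5 to 22.1, against -3.9 to 5.1 at days 4 and 8) and also correlated at -0.38 and -0.3 with the difference of hWT from mock at days 4 and 0 and at -0.23 with that of hG388S from hWT at day 8, and as genes are not independent replicates no p is given. The sequencing run cannot be told apart from the construct, as 0 hWT libraries of day 4 lay in the run of the mutants. An effect of the changes in IRF8 at day 4 stays open as well, untested within a run at that day. Within a run, hG388S and h379_389 differed from hWT by 87 and 2 genes at day 0. At day 8 they differed by 197 and 430, and by 0 in both with a gene length trend subtracted. Those days do not test day 4.

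At day 0 the proliferation list was higher in KO than in WT by a mean log2 fold change of 3.94. A gain at every day that follows from the loss of Irf8 alone is argued against by the means of -0.36 at day 4 and -0.54 at day 8 with 0 of 20 genes higher at either (-0.33 and -0.59 with a gene length trend subtracted), although a fall at day 8 is not shown for the list (adjusted p = 0.41 with an estimated correlation) and WT at day 8 held stromal transcripts (Col1a1 at 77.1 ± 59.3 RPKM). A gene length trend is argued against by the mean of 3.92 once the trend was subtracted. The state of the WT culture at day 0 may account for the pattern and cannot be told apart from the genotype, as there were 0 other groups of WT libraries at day 0. Top2a stood at 1.37 ± 0.284 RPKM in WT at day 0 and 44.8 ± 1.41 at day 8 (n = 3 each). In KO cells at day 0 it stood at 93.4 ± 1.66 RPKM in the first experiment, 14.8 ± 2.65 in mock and 65.9 ± 17.8 in hWT. The median over the list of mean RPKM was 48.2, 15.6 and 28.6 there. The list thus also differed between cultures of KO cells, and its median was not lower in hWT than in mock.

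For contrasts of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real count and the highest among other splits were 4638 and 0 for KO against WT at day 0, 3600 and 5 at day 8, 6074 and 0 for WT from day 0 to day 8, 6672 and 0 for KO from day 0 to day 4, and 6831 and 0 to day 8. They were 8498 and 3999 for hWT against mock at day 0, 5408 and 0 at day 4, 3150 and 0 for hG388S against hWT at day 4, and 3665 and 1 for h379_389 at day 4. In each of these, 1 split, the real one, reached the count. For hG388S against hWT at day 0 the real count was 87 and another split gave 255, so 2 splits reached it. For h379_389 at day 0 the real count was 2, 3 splits reached it, and the split that set the third h379_389 library with the first and second hWT libraries against the rest gave 4298, which points to a structure of these libraries other than the construct.

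For contrasts with more splits, 100 were drawn. The real split alone reached the count for the interaction at day 8 (real 4356, highest other 2968) and hG388S against h379_389 (96 and 22). In macrophages it did so for hWT against mock (4006 and 3043) and hG388S against hWT (5 and 2). A mixed split adds group differences to the spread, which lowers its count, so chance is not excluded by this. For the interaction, labels were exchanged within each day. Its splits thus also break up the difference at day 0 and cannot test the interaction alone. For h379_389 against hWT in macrophages, 6 of 100 splits reached 48 genes and the highest other gave 97, so chance was not excluded there either.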

How the results depend on the processing

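The alternatives of gene length, of 4 libraries left out for their length trend and of 4 macrophage conditions were chosen only after the data were seen. Of the values under settings fixed before the data were examined, single libraries left out aside, 128 stayed within 1.5 times the count or kept the direction, 22 moved and 1 turned, and of the values under the added settings 32 stayed and 8 moved. With a library left out, 153 values stayed and 81 moved. Of the values of named genes in 623 gene and contrast pairs, 411 fell below the threshold, 121 came above it and 2 turned from a direction that had passed. The other 7828 kept direction and side of the threshold, or turned where the gene had not passed in the main fit. Except where stated, the cause was not tested. Over all pairs of groups, replicate numbers showed no pairing: residuals of libraries with the same number had median correlations of -0.005, -0.009 and -0.005, and 8 of 17, 8 of 33 and 22 of 40 libraries correlated most with their own number. Single pairs ranged from -0.35 to 0.9, -0.65 to 0.61 and -0.63 to 0.55. Pairing within a day was not tested apart, and the day 4 libraries numbered 3 of WT and KO shared a length trend (-0.474 and -0.39). With replicate number as a block, 8 genes changed between hG388S and hWT in macrophages, and the other counts stayed within 1.5 times (4908 for KO against WT at day 0, 4085 at day 8). The depth of 0.218 M alignments limits untreated hWT macrophages, and leaving out their second library leaves that one alone, assumed to vary as other groups do.

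Directions turned for 3 values, not counting named genes that had not passed in the main fit. With median-of-ratios scaling, the genes lower in KO at day 0 had a mean log2 fold change of -0.0017 in hWT over mock at day 0, and Irf8 in mock at 4 h of LPS was at 0.41 over IFNg. With the gene length trend subtracted, Fcnb in hWT over mock at day 0 was at 0.04. Genes that had not passed could turn too. Without the shallowest library, H2-Oa in hWT over mock macrophages went from 0.09 to -0.31 and Ccl5 from 0.46 to -0.22. Irf8 in the interaction of hWT with IFNg went from -0.20 to 0.39.

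Counts of genes changed moved to 0 for h379_389 against hWT at day 8, 1 for h379_389 at day 0 and 0 for hG388S at day 8 with the length trend subtracted (2291 and 2109 genes at day 8 had an unadjusted p under 0.05 in limma before it), and to 6 for hG388S at day 8 with scaling. Without the filter, where more genes were tested, they moved to 20 for hG388S in macrophages, 116 for hG388S at day 8 and 4 for h379_389 at day 0. With a pseudocount of 0.1 they moved to 8 and 30 for hG388S and h379_389 in macrophages, 1 for h379_389 at day 0, 1 and 269 for hG388S and h379_389 at day 8, and 54 for hG388S against h379_389. In the 4 macrophage conditions that shared runs, h379_389 differed from hWT by 144 genes. The spread differed between days in the first experiment, with SDs from the group mean of 0.059 to 0.081 at day 0 and 0.26 to 0.487 at day 4. A fit on the groups of the contrast alone, where only their own libraries set the spread, gave 9575 and 258 genes for KO against WT at days 0 and 4 and 5649 for hWT against mock at day 0. It gave 0, 6210 and 1974 for hG388S against hWT and 0, 6173 and 5218 for h379_389 at days 0, 4 and 8 (at day 0, limma over all groups had 2093 and 789 genes at an unadjusted p under 0.05), and 2 and 5815 for the macrophage interactions with IFNg and LPS. Without the 4 libraries with a length trend, KO against WT gave 4261 at day 4 and 7615 at day 8, and the interactions 6736 and 7867. This leaves 1 WT library at day 4 and 1 KO library at day 8, whose spread is taken from the other groups. No conclusion is drawn from these 4 counts, and their rise is not a sign of cleaner data.

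With 1 library left out, the lowest and highest counts were as follows. KO against WT ranged from 3764 to 3832 at day 0, 1155 to 2954 at day 4 and 1740 to 4352 at day 8. Changes from day 0 ranged from 2044 to 6292 and 5187 to 5344 in WT, and from 5800 to 6688 and 5926 to 7316 in KO, for days 4 and 8, with 2594 to 4564 and 3613 to 5041 for the interactions. Counts of hWT against mock ranged from 8145 to 8600, 4345 to 4978 and 2132 to 3040 at days 0, 4 and 8. Counts of hG388S against hWT ranged from 17 to 2508, 1748 to 2384 and 0 to 5, those of h379_389 from 0 to 415, 2561 to 2979 and 0 to 117, and those between the mutants from 15 to 119. In macrophages the ranges were 3626 to 6906 for hWT against mock, 0 to 5374 for hG388S, 25 to 4904 for h379_389, 5929 to 6653 for IFNg, 1882 to 2193, 7817 to 7896 and 6487 to 6653 for LPS, and 1360 to 7178 and 1660 to 2487 for the interactions. The means of the genes lower in KO ranged from 0.2 to 0.29 in hWT, 0.37 to 0.41 in hG388S and 0.33 to 0.38 in h379_389.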

Other observations

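The tests of the altered constructs against mock were chosen only after the result for hWT was seen. The hG388S and h379_389 libraries shared a run with mock at day 4. There 2994 genes changed in hG388S (1549 higher, 1445 lower than in mock) and 3408 in h379_389 (1511 higher, 1897 lower). Dendritic cell genes were higher for 6 of 7 in both (adjusted p = 0.00249 and 0.00194 with an estimated correlation), and proliferation genes for 18 of 20 in hG388S and 17 of 20 in h379_389 (adjusted p = 0.00611 and 0.0144 with an estimated correlation). Lysosome and V-ATPase genes were lower for 10 of 17 in hG388S and 9 of 17 in h379_389 (adjusted p = 0.00631 and 0.0775 with an estimated correlation). Type I interferon-stimulated genes, lower in KO than in WT at day 4, had no common direction against mock. Of 26, 5 were higher and 6 lower in hG388S (mean 0), and 8 and 6 in h379_389 (mean 0.12). By day 8, 14 were higher and 3 lower in hG388S and 15 and 3 in h379_389 (mean 0.65, adjusted p = 0.629 and 0.594 with an estimated correlation). At day 8, 5120 genes changed in hG388S and 5686 in h379_389.

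A hypothesis is that the constructs themselves, and not the run of the hWT libraries, lower osteoclast effector genes and raise class II genes at day 4. The effector list was lower than in mock for 13 of 20 genes in hG388S, by a mean log2 fold change of -0.42 (adjusted p = 0.00983 with an estimated correlation), and for 11 genes in h379_389, where 1 was higher (mean -0.39, camera adjusted p = 0.00194, and adjusted p = 0.0775 with an estimated correlation). All 10 class II genes were higher in both, by means of 2.5 and 2.9. These values, all within a single run as inferred from column names, are compatible with a construct effect that does not need the run. They say nothing of differences between hWT and the altered constructs.

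Every library held Xist and close to no transcripts of the 4 Y-linked genes of the sex-linked list, while the series text speaks of both male and female mice. In WT at day 8 the stromal transcripts differed widely between the 3 libraries, with Col1a1 at 77.1 ± 59.3 RPKM.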
